A study of Mus musculus with 6 samples.

How the data were processed

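Heart tissue was taken from mice 8 weeks after transverse aortic constriction (TAC), a narrowing of the aorta that overloads the left ventricle. Per the labels' protocols, a virus carrying a light-activated channel under the promoter of choline acetyltransferase had been injected into the dorsal vagal motor nucleus of the VNS-TAC mice, so that vagal preganglionic neurones could be activated by light, and the Ctrl-TAC mice had received a virus with the fluorescent protein alone. Messenger RNA was captured with oligo-dT beads, per the labels' protocols. There were 6 samples, 3 in each group, and groups were taken from the sample titles, because a treatment tag in the labels reads VNS for the controls as well.

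The deposited table holds FPKM values (fragments per kilobase of gene, scaled to the size of the library), per the file headers, for 18019 NCBI gene IDs in 6 columns, given to 2 decimals. HISAT, featureCounts version 1.5.0-p3, DESeq version 1.8.3 and the genome build GRCm38 are named in the submitters' processing notes, without the role of each. The annotation and the settings of the counting are not given in the sources used here. The Ctrl-TAC columns were matched to their samples by library name. The VNS-TAC columns are numbered 1 to 3 while the labels number those libraries 4 to 6, so they were used as 3 libraries of the group and are numbered here as in the table. The labels do not say in words that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

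Gene symbols came from an NCBI RefSeq table of the GRCm38.p6 assembly for 17890 IDs and from GENCODE M21 metadata for 16 more, and 113 IDs had no symbol. No mitochondrially encoded gene is among the rows, and Xist was not analysed here. FPKM values carry no library size, but the low values of genes of known length fall on steps of 1 fragment. The steps gave approximate depths of 13660000 to 16080000 fragments per library. The periodicity of the steps was 0.286 to 0.418, against at most 0.223 in 200 shuffles of the gene lengths. These depths are estimates and were used in no test.

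Values were analysed as log2(FPKM + 1), a scale that understates the fold change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 11422. The groups were compared with limma version 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend, 4 residual degrees of freedom) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Before the data were examined, 51 gene lists were fixed, and the 44 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation, camera on ranks and fry, all from limma, were run beside it. The mean of each list per library was compared with a 2-sided exact permutation test over 20 assignments, which cannot give a p below 0.1 with 3 libraries against 3. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

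The text names genes by a rule fixed before the data were examined. It takes the genes past the threshold with the largest changes and no overlap between groups and, where fewer than 5 pass in a direction, those with the smallest unadjusted p until 5 are named. It adds the 4 members with the smallest unadjusted p of each list past its test and of the lists on stress, matrix, macrophages, cytokines, chemokine receptors and cholinergic signalling, 2 members of other lists, and a set of core genes such as Nppa, Col1a1, Ccr2 and Ccrl2. A gene that the rule takes is not reported here. Genes of families with near-identical copies, among them Hspa1a and Hspa1b, Klk1b26 and the haemoglobin genes, are uncertain, because the counting could have split or shared their reads.

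The script was tested on simulated data with the 11422 genes and the spread of the comparison of VNS-TAC with Ctrl-TAC. In 20 simulations with 200 changed genes it recovered 78.8% of those changed by 1 on the log2 scale and 98.8% of those changed by 2, with 10 false calls on average. A list shifted by 0.5 was recovered in 100% of simulations and 0.05 unshifted lists were called on average. The simulated genes vary independently of each other, which real genes do not. Each gene also had the same spread in both groups, set to its moderated variance from limma. The real VNS-TAC libraries varied more, with an SD of the collagen and matrix list mean of 0.525 against 0.142 in Ctrl-TAC. The recovered shares therefore do not tell how often real changes of these sizes would be found.

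Alternatives were other pseudocounts, other filters, rescaling by size factors, quantile normalization, rescaling every library to the same sum, limma without the trend, in its robust form and with array weights, and each library left out in turn. The default estimate of array weights did not converge, and the gene-by-gene estimate was used. Removal of a GC content or gene length trend from each library was added after the data were seen.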

Results

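Gene expression was measured in 3 VNS-TAC and 3 Ctrl-TAC libraries from mouse hearts, 8 weeks after the aorta was narrowed. The estimated depth was about 13660000 to 16080000 fragments per library, and the FPKM values of a library summed to between 516493 and 585330. The 3 Ctrl-TAC libraries resembled each other, with correlations across genes of 0.988 to 0.992, while the VNS-TAC libraries correlated with each other at 0.941 to 0.979. The VNS-TAC libraries did not group together. VNS-TAC 2 correlated more with each Ctrl-TAC library (0.983 to 0.987) than with VNS-TAC 1 (0.979) or VNS-TAC 3 (0.971). VNS-TAC 1 and VNS-TAC 3 also each correlated more with every Ctrl-TAC library (0.968 to 0.974 and 0.947 to 0.952) than with each other (0.941). Principal component 1 (48% of the variance) set library VNS-TAC 3 apart at 46.4, with the other libraries between -16.6 and 4.64. Principal component 2 (33.9%) set VNS-TAC 1 apart at 36.5. In VNS-TAC 1 the deviation of genes from their mean also followed their GC content, with a Spearman correlation across genes of 0.549, against -0.416 to 0.024 in the other libraries. The log2 fold change of VNS-TAC against Ctrl-TAC itself correlated across genes with GC content at 0.376 and with gene length at -0.16 (Spearman). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were above 1 FPKM in all 6 libraries and all lowest in VNS-TAC 1, with Ddx3y at 3.75 FPKM there against 8.65 to 15.9 and Eif2s3y at 8.06 against 17.0 to 27.8.

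**Figure D1:**
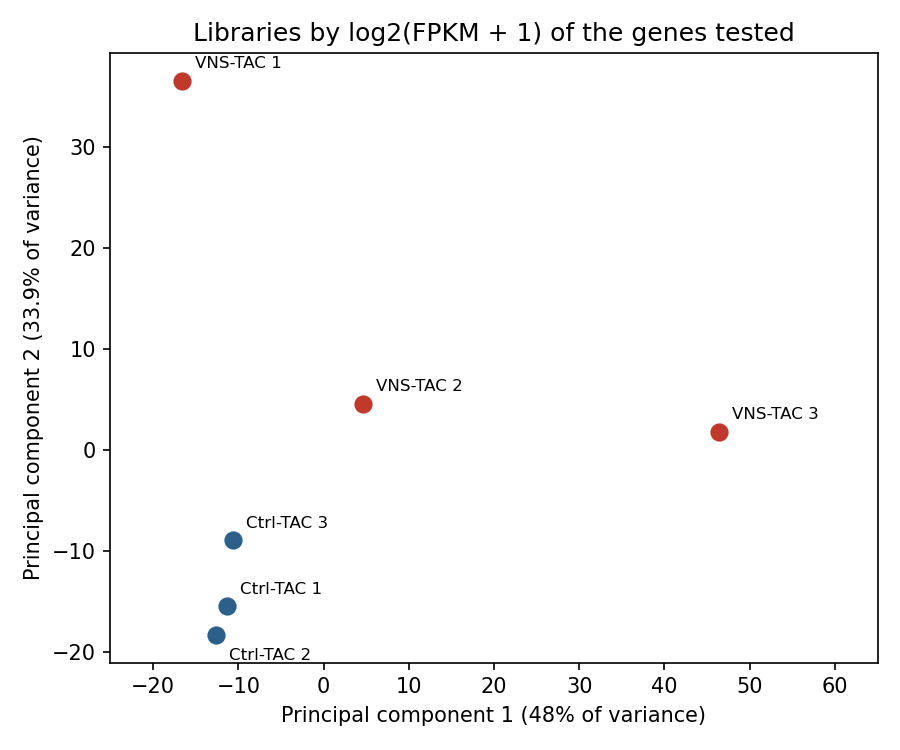
Scores of the 6 libraries on principal components 1 and 2 of log2(FPKM + 1), with VNS-TAC in red and Ctrl-TAC in blue. VNS-TAC 3 lies at 46.4 on component 1 and VNS-TAC 1 at 36.5 on component 2, and the 3 Ctrl-TAC libraries lie together.

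The comparison of VNS-TAC with Ctrl-TAC asks how activation of vagal neurones alters gene expression in the overloaded heart. By fold change, neutrophil markers differed most of the 44 gene lists, with a median log2 fold change of 1.69. S100a9 and S100a8, which together form the neutrophil protein calprotectin, stood at 29.2 ± 11.2 and 26.9 ± 12.9 FPKM (SD, n = 3) in VNS-TAC and at 1.05 ± 0.73 and 1.20 ± 0.73 FPKM in Ctrl-TAC. Genes of the extracellular matrix were lower, with a median log2 fold change of -1.02 over 38 genes. No single gene passed the adjusted threshold in limma, and S100a9 came nearest at an adjusted p of 0.0508.

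At an unadjusted p under 0.05, limma gave 1719 genes, 433 higher and 1286 lower in VNS-TAC, where 571 would be expected by chance. In 25.4% of genes the 3 values of one group all lay above the 3 of the other, against 10% by chance, 915 higher and 1990 lower. Of the genes at an unadjusted p under 0.05, 25.2% were higher, and this share was 46.7% with size factors, 54.4% after quantile normalization and 10.8% after rescaling every library to the same sum, so the excess of lower genes depended on the scaling. The share of higher genes was 42.9% with the GC trend removed and 48.3% with the length trend removed. The median log2 fold change of all genes was -0.08, and 0.01 after quantile normalization. Size factors or quantile normalization put S100a9 and S100a8 past the adjusted threshold (2 genes). Array weights put 257 higher and 759 lower genes past it. They gave VNS-TAC 1 and VNS-TAC 3 weights of 0.246 and 0.247 against 2.82 for VNS-TAC 2, so the VNS-TAC side of that fit rested mainly on 1 library.

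Genes with the smallest unadjusted p, all of which missed the adjusted threshold, were S100a9, S100a8, Klk1b26, Ngp and Pla2g12a among those higher and Egr2, Col8a1, Ecrg4 and Cd83 among those lower. S100a9 (chromosome 3, 90692630 to 90695721, GRCm38) had a log2 fold change of 3.88 ± 0.33 (SE), and its neighbour S100a8 (chromosome 3, 90669071 to 90670034) one of 3.63 ± 0.37 with an adjusted p of 0.0936. Pla2g12a, a secreted phospholipase, was at 57.9 ± 1.70 FPKM against 34.5 ± 1.71 (SD, n = 3). Cd83, a marker of activated dendritic cells, was at 0.95 ± 0.18 FPKM against 3.07 ± 0.39. Klk1b26 was at 2.72 ± 1.10 against 0.14 ± 0.13 FPKM, but it belongs to a family of close copies.

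**Figure D2:**
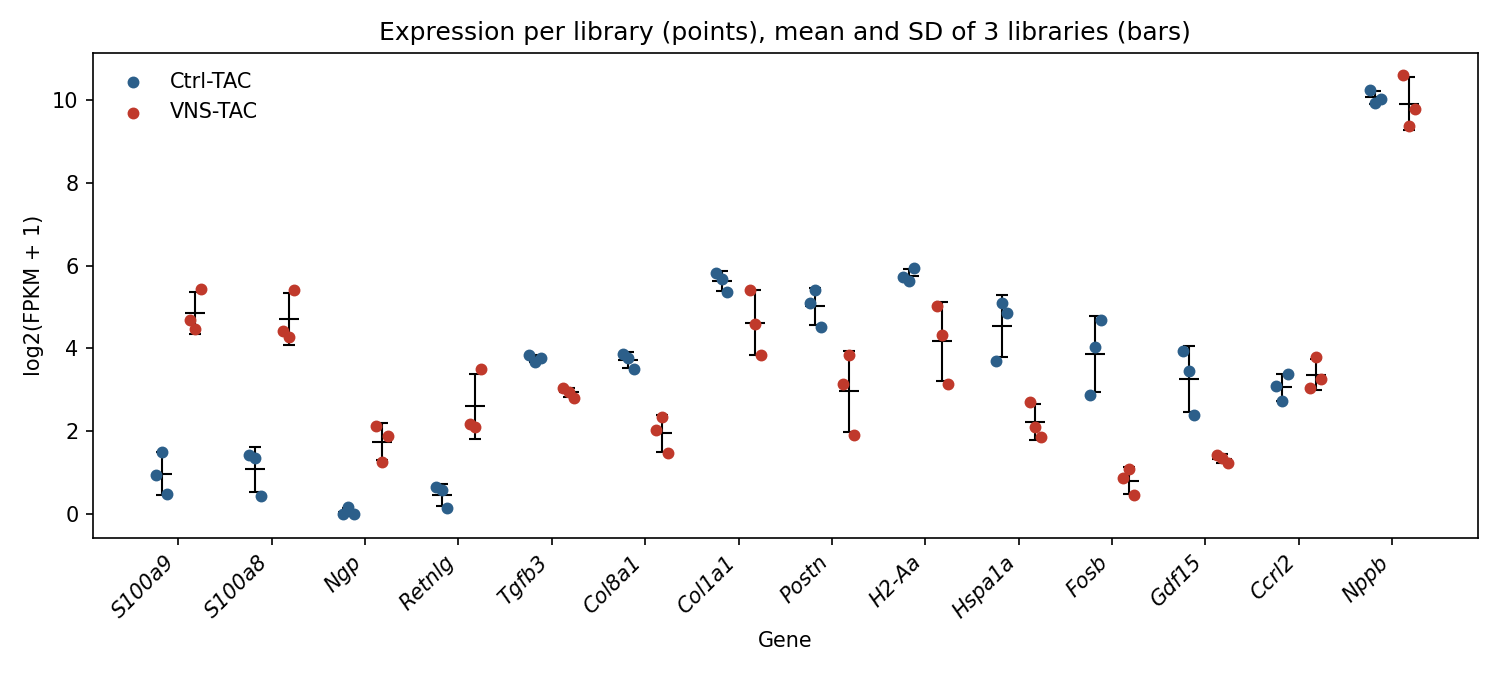
Expression of named genes as log2(FPKM + 1), with a point for each library and bars for the mean and SD of the 3 libraries of a group, VNS-TAC in red and Ctrl-TAC in blue. S100a9 and S100a8 are separated by group, and Nppb and Ccrl2 overlap.

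Of the 44 gene lists tested with camera, 5 were higher and 7 lower in VNS-TAC at an adjusted p under 0.05. None of the 44 passed with an estimated correlation (smallest adjusted p = 0.503), and 3 had an unadjusted p under 0.05 in that test. Among the 12 lists past camera, the estimated correlation ran from -0.031 (TGF-beta pathway) to 0.88 (ribosomal protein genes). By fry, 3 lists passed, namely neutrophil markers, the TGF-beta pathway and matrix remodelling enzymes. In the exact permutation test of list means, 20 of the 44 lists reached the lowest possible p of 0.1, namely the neutrophil list, all 7 lower lists and 12 that did not pass camera, whereas the ribosomal, antioxidant, glucose and oxidative phosphorylation lists gave 0.2, 0.2, 0.4 and 0.5.

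Neutrophil markers rose in VNS-TAC, with a median log2 fold change of 1.69 (camera adjusted p = 1.18e-11, and 0.503 with an estimated correlation). All 9 tested members were higher on average, and 7 of them did not overlap between the groups. Hdc and G0s2, named after their values were seen, overlapped. Hdc was at 1.05, 0.96 and 1.41 FPKM in VNS-TAC 1, 2 and 3 against 1 to 1.14 in Ctrl-TAC. G0s2 was at 81.9, 45.7 and 27.0 FPKM against 33.5 to 39.6. Of the 9 members, 7 passed when adjusted over the list alone and 0 over all genes. Only 9 of 23 matched members passed the expression filter, and with no filter the mean log2 fold change of the list less that of all genes was 1.06, against 1.92 with it. Ngp, a protein of neutrophil granules, was at 3.34, 1.38 and 2.67 FPKM in the VNS-TAC libraries and at 0, 0.12 and 0 in Ctrl-TAC. Retnlg was at 5.74 ± 4.03 FPKM against 0.39 ± 0.25 (SD, n = 3), a log2 fold change of 2.14, or 3.53 with a pseudocount of 0.1. The mean of 4 haemoglobin genes, which mark blood, was 8.25, 5.92 and 2.36 on the log2 scale in VNS-TAC 1, 2 and 3, and 5.28 to 6.85 in Ctrl-TAC.

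Collagen and matrix genes fell, 36 of 38 being lower (camera adjusted p = 4.08e-12; adjusted p = 0.548 with an estimated correlation), and 25 passed when adjusted over the list alone, 0 over all genes. Col8a1 was at 2.97 ± 1.14 FPKM against 12.2 ± 1.72 (SD, n = 3), P4ha1, a collagen prolyl hydroxylase, at 9.26 ± 2.88 against 27.7 ± 4.77, and Fmod at 1.77 ± 0.97 against 6.76 ± 0.74. Col1a1 and Col3a1, the main fibrillar collagens, were at 26.1 ± 14.5 and 24.2 ± 21.2 FPKM against 48.8 ± 7.99 and 59.7 ± 11.3, but both overlapped, with VNS-TAC 1 above Ctrl-TAC 3, and Col1a1 went from a log2 fold change of -1.01 to -0.62 without VNS-TAC 3. The list mean relative to Ctrl-TAC was -0.58, -0.82 and -1.59 in VNS-TAC 1, 2 and 3, and without VNS-TAC 3 the median log2 fold change was -0.68. Fibroblast markers fell as well, with 18 of 22 lower (camera adjusted p = 0.0175; adjusted p = 0.548 with an estimated correlation), but 7 of them are also in the matrix list. Their mean log2 fold change less that of all genes was -0.554, and -0.316 without VNS-TAC 3. Postn, expressed by activated fibroblasts, was at 7.96 ± 5.27 FPKM against 32.4 ± 9.89.

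The TGF-beta pathway drives fibroblast activation. Of its genes, 18 of 23 were lower (camera adjusted p = 0.00117, and 0.503 with an estimated correlation). The list holds ligands, receptors, Smads and direct targets together, so its RNA does not measure the activity of the pathway. The estimated correlation of the list was -0.031, and camera with that estimate gave an unadjusted p of 0.0140. Of the 12 lists past camera, its mean differed least between the VNS-TAC libraries, at -0.43, -0.40 and -0.37 relative to Ctrl-TAC. The ligand gene Tgfb3 was at 6.66 ± 0.61 FPKM against 12.5 ± 0.85 (SD, n = 3) and Tgfb2 at 3.39 ± 0.17 against 5.84 ± 1.37. Of the list, 7 members passed when adjusted over the list alone. Matrix remodelling enzymes did not pass camera (adjusted p = 0.209), with 15 of 21 lower.

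Dendritic and antigen presentation genes fell, all 10 being lower (camera adjusted p = 1.84e-04; adjusted p = 0.548 with an estimated correlation). The class II genes H2-Aa, H2-Ab1 and H2-Eb1 were at 19.6 ± 11.96, 17.2 ± 11.4 and 12.1 ± 7.59 FPKM against 53.5 ± 6.42, 46.9 ± 3.58 and 29.9 ± 2.51 (SD, n = 3), and the list mean relative to Ctrl-TAC was -0.341, -0.987 and -1.73 in VNS-TAC 1, 2 and 3. Without VNS-TAC 3 the log2 fold change of H2-Ab1 went from -1.65 to -1.03 and that of H2-Eb1 from -1.46 to -0.88. Less that of all genes, the mean log2 fold change of the list was -0.925, and -0.541 without VNS-TAC 3 or -0.485 with no filter. The filter kept 10 of 25 matched members. Interferon response genes fell with 32 of 38 lower (camera adjusted p = 0.00257; adjusted p = 0.548 with an estimated correlation), a call lost without VNS-TAC 2 or Ctrl-TAC 3 and with a filter at a mean of 5 FPKM (adjusted p = 0.0999, 0.0797 and 0.537). The mean of this list less that of all genes was -0.227, and -0.161, -0.137 and -0.094 in these 3 settings. Rsad2, an antiviral gene, was at 2.80 ± 0.47 FPKM against 6.15 ± 0.58.

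Heat shock and unfolded protein response genes fell, with 29 of 36 lower (camera adjusted p = 0.00415; adjusted p = 0.548 with an estimated correlation), a call lost without VNS-TAC 2 (adjusted p = 0.242), where the mean less that of all genes was -0.231, against -0.325 with it. The 4 members with the smallest p were the cytosolic chaperone genes Hsph1, Dnaja1, Hspa1a and Hspa1b, with Hsph1 at 6.79 ± 2.27 FPKM against 28.5 ± 8.94 (SD, n = 3). The median log2 fold change of the list was -0.219 and the mean -0.419. Its heat shock members and its unfolded protein response members were not tested apart. Immediate early genes are early-response genes, many of them transcription factors, and were listed as a check of handling. They fell with 22 of 28 lower (camera adjusted p = 0.0172; adjusted p = 0.548 with an estimated correlation), a call lost without VNS-TAC 2 or VNS-TAC 3 and with a filter at a mean of 5 FPKM (adjusted p = 0.108, 0.161 and 0.14). The mean of this list less that of all genes stayed lower in these 3 settings, at -0.428, -0.331 and -0.381 against -0.489. Fosb was at 0.84, 1.13 and 0.37 FPKM in VNS-TAC and at 6.28, 15.4 and 24.9 in Ctrl-TAC. Fos, named after its values were seen, was at 16.17, 1.8 and 1.23 FPKM in VNS-TAC and at 6.44 to 12.15 in Ctrl-TAC. The list mean relative to Ctrl-TAC was -0.219, -0.688 and -0.841 in VNS-TAC 1, 2 and 3, and -0.127 to 0.07 in Ctrl-TAC. For these and the heat shock genes, a difference in handling between the groups was not tested and cannot be told apart from the treatment.

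Cytosolic ribosomal protein genes rose by a small amount, all 77 being higher with a median log2 fold change of 0.35 (camera adjusted p = 5.73e-23; adjusted p = 0.548 with an estimated correlation). The list mean was 0.26, 0.08 and 0.67 in VNS-TAC 1, 2 and 3, against -0.08 to 0.10 in Ctrl-TAC, and without VNS-TAC 3 the median was 0.19. Less that of all genes, the mean log2 fold change of the list was 0.432, and 0.209 with quantile normalization or 0.2 with array weights. Oxidative phosphorylation genes of the nucleus rose with 65 of 76 higher (camera adjusted p = 3.77e-07; adjusted p = 0.855 with an estimated correlation), but VNS-TAC 3 lay at -0.16 relative to Ctrl-TAC, the call was lost without VNS-TAC 1, and the mean log2 fold change of the list less that of all genes went from 0.225 to -0.018 after quantile normalization, to 0.061 without VNS-TAC 1 and to 0.397 without VNS-TAC 3. Glucose metabolism and antioxidant genes passed camera (adjusted p = 0.0059 and 0.0272; adjusted p = 0.548 with an estimated correlation for both), with 19 of 31 and 22 of 36 members higher. Both calls were lost without VNS-TAC 1 and after quantile normalization, and the antioxidant call also with the length trend removed. Less that of all genes, the mean of the glucose list was 0.17, and 0.093 without VNS-TAC 1, 0.035 after quantile normalization and 0.256 without VNS-TAC 3. For the antioxidant list it was 0.199, and 0.174 without VNS-TAC 1, 0.126 after quantile normalization and 0.176 with the length trend removed. Aldoa, a glycolytic enzyme, was at 2802 ± 425 FPKM against 2021 ± 135 (log2 fold change 0.46, and 0.26 after quantile normalization), and Gstm1, a glutathione transferase, at 236 ± 67.7 against 141 ± 14.0 (SD, n = 3).

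**Figure D3:**
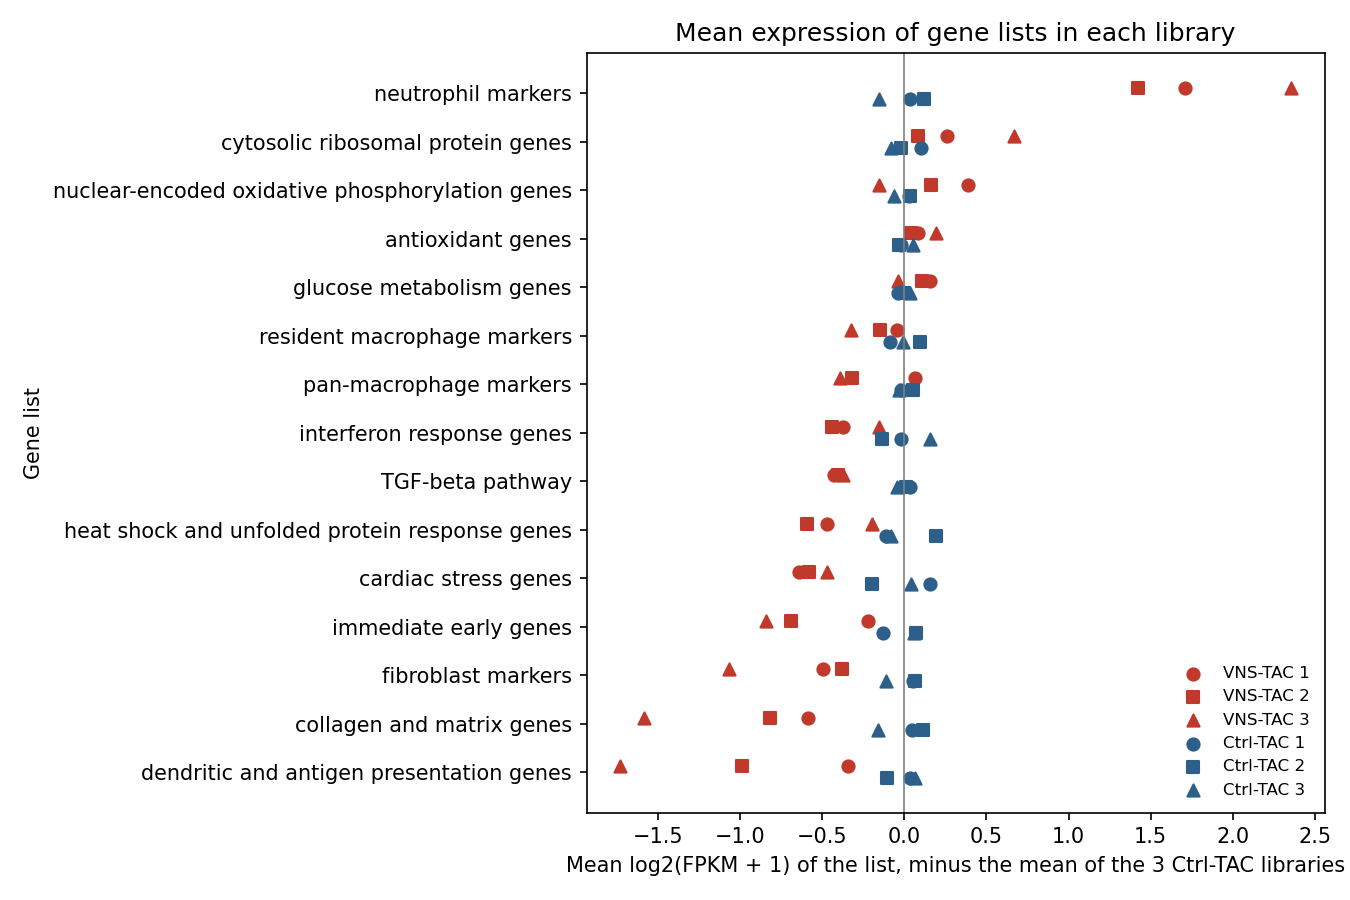
Mean log2(FPKM + 1) of gene lists in each library, minus the mean of the 3 Ctrl-TAC libraries, with VNS-TAC in red, Ctrl-TAC in blue and a symbol for each library number. Neutrophil markers lie at 1.42 to 2.36 in VNS-TAC, and collagen and matrix genes at -1.59 to -0.58.

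Cardiac stress genes did not pass (camera adjusted p = 0.0629), although 18 of 21 were lower, and they passed in 9 of 21 alternatives. Gdf15, a stress-induced cytokine, was at 1.53 ± 0.19 FPKM against 9.47 ± 5.05 (SD, n = 3) and Xirp2 at 32.3 ± 15.7 against 114 ± 36.0. Acta1, skeletal actin, was at 812 ± 663 FPKM against 2838 ± 1213 with no overlap between the groups, a log2 fold change of -2.44 ± 0.98 (SE) that missed the threshold (limma adjusted p = 0.31) and was -1.19 without VNS-TAC 3. The natriuretic peptide genes Nppa and Nppb overlapped, at 4818 ± 2595 and 1030 ± 468 FPKM against 4842 ± 2215 and 1074 ± 120. Nppa is also 1 of 16 atrial markers, fixed as a check of dissection (camera adjusted p = 0.209). Relative to Ctrl-TAC, the mean of this list was -0.425, 0.028 and 0.479 in VNS-TAC 1, 2 and 3, and 0.232, -0.682 and 0.45 in Ctrl-TAC. In the same order Nppa was at 2645, 4118 and 7691 FPKM, and at 4966, 2567 and 6992. Whether the amount of atrial tissue in the samples shaped the Nppa values was not tested. The myosin gene Myh6 was at 5281 ± 1792 FPKM against 5166 ± 633, and Myh7 at 165, 435 and 5427 FPKM in VNS-TAC 1, 2 and 3 against 877 ± 265.

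Macrophage lists did not pass, with camera adjusted p = 0.302 for pan-macrophage markers (21 of 26 lower), 0.887 for resident macrophages (14 of 21 lower) and 0.673 for monocytes and the macrophages derived from them (8 of 14 higher). The monocyte list holds S100a8 and S100a9, which are also in the neutrophil list, and its mean log2 fold change was 0.389 but its median 0.053. The pan-macrophage list passed without VNS-TAC 1 (adjusted p = 8.47e-04) and with array weights (adjusted p = 0.00401). Ccrl2, an atypical receptor for chemerin, was at 9.54 ± 2.86 FPKM against 7.50 ± 1.89 (SD, n = 3; limma adjusted p = 0.55), and Cd68 at 8.03 ± 2.71 against 8.00 ± 0.74. Ccr2, Il1b, Tnf and Il6 were under the expression filter, with means of 0.377, 0.317, 0.27 and 0.137 FPKM in VNS-TAC and 0.533, 0.6, 0.217 and 0.167 in Ctrl-TAC. Cytokines and their receptors (adjusted p = 0.842), chemokine receptors (0.24) and cholinergic and adrenergic signalling genes (0.234) did not pass camera either. Chrm2, the cardiac muscarinic receptor, was at 21.1 ± 11.3 FPKM against 21.6 ± 2.65, and Adrb1 at 6.95 ± 2.80 against 7.06 ± 0.82.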

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

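The GC and length corrections were chosen after seeing the data, and the cause of a change was not tested. No paired analysis was possible because the numbers of the VNS-TAC columns do not settle which labelled sample each holds. A replicate block was therefore not run. The sample titles number both groups 1 to 3, but the labels number the VNS-TAC libraries 4 to 6 and the Ctrl-TAC libraries 1 to 3. These numbers do not show that the samples were paired. Of 1560 values for 88 genes taken by the rule under the alternatives, 73 gained a call and 28 reversed, in 9 genes, and as no gene passed in the main fit none had a call to lose. Against 0 genes higher and 0 lower, there were 1 and 0 with a mean of at least 5 FPKM or the length trend removed, and 2 and 0 with size factors, quantile normalization, the GC trend removed or an adjusted p under 0.1. Array weights, under which the VNS-TAC side rested mainly on VNS-TAC 2, gave 257 and 759. Unadjusted p under 0.05 gave 433 and 1286, and 111 and 495 with a 1.5-fold change. Leaving out single libraries gave 0 to 2 higher and 0 to 2 lower. Against 5 lists higher and 7 lower, there were 8 higher with no filter, 3 and 12 with quantile normalization, 10 higher with array weights, 0 and 0 with an estimated correlation, and 1 and 2 by fry. Leaving out single libraries gave 2 (without VNS-TAC 1) to 10 (without VNS-TAC 3) higher and 5 to 9 lower.

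Log2 fold changes that reversed were, with size factors, Nppa 0.05, Myh6 0.05 and Cd68 0.04; with quantile normalization, Cd68 0.06 and Adrb1 0.02; with array weights, Myh6 0.28, Adrb1 0.14 and Atp2a2 0.01; with the length trend removed, Nppa 0 and Cd68 0.01; and with the GC trend removed, Chrm2 0.07. With single libraries left out, values ran from -0.44 to 0.33 for Nppa, -0.49 to 0.13 for Nppb, -0.19 to 0.3 for Myh6, -1.66 to 0.86 for Myh7, -0.9 to 0.31 for Ccn2, -0.27 to 0.1 for Cd68, -0.54 to 0.26 for Chrm2, -0.28 to 0.25 for Adrb1 and -0.28 to 0.01 for Atp2a2. For lists, by the mean log2 fold change less that of all genes, oxidative phosphorylation turned to -0.018 with quantile normalization, and resident macrophage markers ran from -0.182 to 0.025 with single libraries left out. Camera's direction turned for these and, at 0.277 with array weights, for monocyte markers. The glucose list had a difference of -0.047 by medians per library.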

Other observations

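The tests on the VNS-TAC 3 library, on fibroblasts, on haemoglobin, on the other neutrophil genes, on each of the ribosomal and oxidative phosphorylation lists alone, and the GC and length corrections were chosen after the results they bear on, or the data, had been seen. Library VNS-TAC 3 carried high acute-phase genes, named here after their values were seen. Saa3 was at 123 FPKM there, at 6.37 and 1.19 in VNS-TAC 1 and 2 and at 0 to 0.27 in Ctrl-TAC. Lcn2 was at 80.4 FPKM, against 12.2 and 9.31 in the other VNS-TAC libraries and 2.27 to 3.07 in Ctrl-TAC. It is also counted among the neutrophil markers. Serpina3n was at 178 FPKM, against 27.9 and 24.5 in the other VNS-TAC libraries and 8.48 to 11.7 in Ctrl-TAC. The glucocorticoid-responsive gene Fkbp5 was at 61.0 FPKM in VNS-TAC 3, 7.25 and 17.0 in VNS-TAC 1 and 2, and 6.71 to 11.2 in Ctrl-TAC. Acta1 was at 84.9 FPKM in VNS-TAC 3, 968 and 1382 in VNS-TAC 1 and 2, and 1569 to 3986 in Ctrl-TAC. In VNS-TAC 1 the chemokine gene Ccl8 was at 30.7 FPKM, against 2.07 to 5.45 elsewhere.

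Lists with under 5 tested members were described by mean FPKM. T and NK cell markers were at 0.436 ± 0.015 against 0.498 ± 0.026 (SD, n = 3), B and plasma cell markers at 2.73 ± 0.99 against 2.42 ± 0.295, mast cell markers at 1.34 ± 0.473 against 1.25 ± 0.063, lung genes at 19.7 ± 0.703 against 22.9 ± 2.26, and thymus genes at 3.50 ± 0.557 against 3.66 ± 0.164. Ly6c2, a marker of monocytes, was under the filter at 0.783 ± 0.206 against 0.147 ± 0.046 FPKM.

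In 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 1719 genes at an unadjusted p under 0.05, and the highest of the others gave 650. Genes without overlap numbered 2905 in the real split and 447 to 1839 in the others. For gene lists, 7 of the 10 splits gave as many as the 12 of the real split, and the highest of the others gave 18. With 10 splits no share under 0.05 can be reached. The number of list calls at the preset correlation therefore does not set the real grouping apart.

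Neutrophil genes were higher in VNS-TAC. More blood in all 3 VNS-TAC hearts is argued against, since haemoglobin in 2 of the 3 VNS-TAC libraries lay at or below the highest Ctrl-TAC library. VNS-TAC 1, at 8.25, lay above that library (6.85), VNS-TAC 2, at 5.92, within the Ctrl-TAC range, and VNS-TAC 3, at 2.36, below it. Haemoglobin does not measure the neutrophils that the blood held, so a higher number of them in the blood is not excluded. A GC trend is argued against as well, since the median log2 fold change was 1.76 with the trend removed and 1.69 before. Of 21 other members of the list, 57.1% had 3 VNS-TAC values above the 3 of Ctrl-TAC, but 7 of the 21 are tested genes whose rise is in question, and of the 14 under the filter 7 did and 0 were lower, against 2.5% and 10% of 6219 other genes under it. Whether there were more neutrophils, in the tissue or in the blood it held, or a higher expression of these genes was not tested. Whether the rise followed the vagal activation or another difference between the samples was not tested either.

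Collagen and matrix genes were lower in VNS-TAC. The median log2 fold change was -1.01 with the GC trend removed and -0.68 without VNS-TAC 3, against -1.02, so neither accounts for the whole difference. For fewer fibroblasts, a first set of 9 fibroblast genes picked by hand had a median of -0.211, but it left out markers that were lower, such as Meox1, so all 15 fibroblast markers outside the matrix list were used. Their median was -0.388, above that of the matrix list by 0.635 (mean difference 0.575, SE 0.153), and by 0.466 without VNS-TAC 3, under the bound of 0.5 set for the test. Fewer fibroblasts may therefore account for part of the difference, and lower matrix expression per fibroblast is a hypothesis that these bulk values leave open.

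Ribosomal protein and oxidative phosphorylation genes were higher in VNS-TAC. Relative to all genes, the median log2 fold change over both lists was 0.345, and 0.315 with the GC trend removed, 0.295 with the length trend removed and 0.296 without VNS-TAC 1. The joint value hid a difference between the lists. Without VNS-TAC 1 the ribosomal list kept 0.424 of 0.433, while the oxidative phosphorylation list went from 0.223 to 0.062, so the rise of the latter may rest on that library. The ribosomal rise was smaller in other settings. Its mean log2 fold change less that of all genes went from 0.432 to 0.296 without VNS-TAC 3. With quantile normalization it was 0.209, and with array weights 0.2. No biological explanation was tested.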
